A study of Homo sapiens with 2 samples.

How the data were processed

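FAIRE DNA was sequenced from 2 replicate libraries of HUVEC. Per the labels' protocols, cells were crosslinked with formaldehyde, lysed and sonicated, the diluted lysate was passed over a DNA clean-up column, and libraries were made with a TruSeq kit and read at 50 bp. A portion of the sonicated material was kept as an input control, per the labels' protocols, while the design text calls a control experiment unnecessary. Whether an input entered the peak calling is not given in the sources used here. Nothing in the labels says whether the replicates were separate cultures.

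The submitters' processing notes name Bowtie, MACS2 and the hg19 genome build, with no versions, roles or order. The deposited file is a single peak list with a start, an end, a name beginning with MACS and a score for each peak. The score is the authors' own value for the peak. Its scale is not given in the sources used here, so the score served only to rank and filter peaks within the list. Whether the replicates were pooled before peak calling, the score or significance limit, and any filter on peaks are not given in the sources used here. These choices set how many weak peaks are listed, and the width and score of each. A single list with no mark of replicate allows no replicate error, no test between libraries and no check that the libraries differ. It holds no read counts, so the depth per library is unknown.

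The autosomal peaks were analysed, and the sex chromosomes were left out of every value. Coordinates are hg19, counted from 1. The length considered on each autosome ran from its first to its last peak, without the 21 peak-free stretches of 1 Mb or more. This length comes from the peaks themselves, since chromosome lengths and assembly gaps of hg19 were not used here. Top classes (10%, 1% and 0.1%) and the lower 50% were taken from the score over all autosomal peaks.

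Peak spacing was the distance between the midpoints of neighbouring peaks. It was compared with 100 placements in which the peaks of each stretch were set down at random without overlap, and with 100 placements that also kept the number of peaks in each 1 Mb window. These placements ignore sequence content, and reads can be aligned better to some sequence than to other. Pair densities counted all pairs of midpoints at a given separation, and their standard errors came from leaving out each autosome in turn. The relabelling test exchanged scores among the peaks of each chromosome, 100 times. Runs of high-scoring peaks needed 5 or more top 10% peaks with midpoints at most 10 kb apart. Windows of 1 Mb started at position 1 and counted only where they lay inside a stretch considered. Intervals are 95% Wilson intervals for shares and Poisson intervals for counts. Peaks of one list are not replicates, and no p-values were computed.

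The procedures were tested on simulated lists of 226856 peaks. A uniform list gave a fold of 1.00 for neighbours within 2 kb, and 8.15 of 8.61 planted percentage points of near neighbours were recovered. Random score labels gave a fold of 1.01 for top 10% peaks beside each other, and labels planted in neighbouring pairs gave 3.87. The ratio of pair densities was 0.998 in a uniform list and 0.516 where a deficit of 0.5 had been planted. The variance over mean of counts per window was 0.993 times that of another uniform list, and 8.52 where thinned windows were made to give 8.20. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

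The number of peaks, their width, score, density by autosome and spacing were chosen before the data were examined, as were the alternatives of keeping the top 50% or top 10% by score and of merging intervals within 500 bp. The rule for named items, fixed at the same time, took the 10 highest-scoring autosomal peaks, and the genes at peaks and in 12 gene lists. Genes, promoters, genomic location, CpG content, sequence motifs and GGAA repeats were not analysed here, because they need hg19 annotation or sequence, which was not used here. The pair densities with their separations, the relabelling test, the runs, the 1 Mb windows and every region named from them, the comparison of shares in the top 10% between autosomes and the peak ranked 14 were chosen after the values were seen. The alternatives added then were peak-free stretches of 250 kb, the lower 50% of peaks, distances of 2 and 50 kb for the relabelling test, windows shifted by 500 kb, and the score and merging alternatives of the pair density ratio.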

Results

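Open chromatin was profiled in human umbilical vein endothelial cells (HUVEC), a cultured cell type from the lining of a blood vessel, with a column-based form of FAIRE-seq. FAIRE (formaldehyde-assisted isolation of regulatory elements) recovers the DNA of crosslinked, sonicated chromatin that is not held by protein, so that sequenced fragments pile up where nucleosomes are sparse. The series is titled for a small-molecule screen against abnormal chromatin accessibility, and the samples analysed here formed 1 group of 2 replicate libraries. The values came from 1 peak list in hg19 coordinates that does not mark replicates, so no value below has a replicate error and no groups were compared. The list gives no read counts, and the depth behind each peak is unknown.

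The open chromatin of HUVEC was listed as 226856 narrow intervals on the 22 autosomes, which together covered 71.96 Mb, or 2.67% of the 2690 Mb considered. The density was 84.3 peaks per Mb. Widths ranged from 200 to 2267 bp with a median of 277 bp, and 507 peaks were wider than 1000 bp. Most peaks had low scores and a small set had very high ones. The authors' score per peak had a median of 6.95, a 90th percentile of 20.4, a 99th percentile of 66.6 and a maximum of 197.69.

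High-scoring peaks were also the wider ones. The 22688 peaks in the top 10% by score had a median width of 418 bp, against 245 bp for the 113377 peaks in the lower 50%, and held 14.6% of the covered sequence. Spearman's rho of width with score was 0.456 across peaks, which are not independent replicates. The narrowest width, 200 bp, was shared by 16946 peaks (7.47%). That width was found for 13.1% of the lower 50% by score and 0% of the top 10%.

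The 10 highest-scoring peaks lay on 8 autosomes and stood 384 to 599 bp wide. The highest was at chromosome 21, 9825350 to 9825733, with a score of 197.69, and the peak ranked 14 (score 144.03; 9825882 to 9826350) began 148 bp beyond it. This pair lay before a peak-free stretch of 3.19 Mb, in a part of chromosome 21 where 46 of 258 peaks (17.8%) were in the top 10%. After the stretch, 269 of 2988 peaks were, and the ratio of the shares was 1.98 (95% interval 1.49 to 2.64, which treats peaks as independent). The next scores were 189.70 at chromosome 18, 34043114 to 34043542, and 160.85 at chromosome 14, 61774878 to 61775348. A score of 159.57 was listed at chromosome 10, 65467044 to 65467581, and one of 153.97 at chromosome 4, 113004313 to 113004803.

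The remaining 5 of these peaks scored between 151.34 and 153.41. They were at chromosome 2, 159793436 to 159794004, chromosome 21, 27298198 to 27298637, and chromosome 10, 33321334 to 33321932. The last of them were at chromosome 1, 12664241 to 12664723, and chromosome 11, 74465898 to 74466448. The surroundings of the 10 peaks differed widely. The chromosome 14 peak had 19 other peaks with midpoints within 50 kb, 4 of them in the top 10%, whereas the chromosome 1 peak had 2 and none in the top 10%. The median number of other peaks within 50 kb was 12.5 for the 10 peaks and 10 for 1000 randomly drawn peaks.

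Peaks were most dense on chromosomes 4, 13 and 6, with 101.2, 100.8 and 97.9 peaks per Mb. They were sparsest on chromosomes 19 and 22, with 41.9 and 47.0 peaks per Mb, and the ratio of chromosome 4 to chromosome 19 was 2.42 (95% Poisson interval 2.32 to 2.53). Among high-scoring peaks the order of chromosomes 4 and 19 turned round. Chromosome 19, known as a gene-dense chromosome, had 9.19 peaks of the top 10% per Mb, and chromosome 4, known as a gene-poor one, had 7.17, a ratio of 1.28. Other autosomes followed this order only in part. Dense chromosome 13 had 7.63, and sparse chromosomes 17 and 20 had 9.90 and 8.80. Dense chromosome 6, however, had 9.27, and sparse chromosomes 16 and 22 had 7.62 and 8.34. The difference in total density lay among the peaks below the top 10%. Of the lower 50% by score, chromosome 4 had 55.0 per Mb and chromosome 19 had 14.9.

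The share of peaks that were in the top 10% by score was 21.96% on chromosome 19 (506 of 2304 peaks, 95% Wilson interval 20.3 to 23.7%). It was 17.7% on chromosome 22 (16.0 to 19.7%), 15.7% on chromosome 17 (14.7 to 16.7%) and 7.08% on chromosome 4 (6.73 to 7.46%). The 5 autosomes with the fewest peaks per Mb, chromosomes 16, 17, 19, 20 and 22, were also the 5 with the largest shares. Top 10% peaks per Mb varied 1.44-fold between autosomes and all peaks per Mb 2.42-fold, so this ranking largely restates that by density. Shares on these were 13.7% or more, and those on the other autosomes were 11.6% or less. Covered sequence followed the number of peaks, with 31.8 kb per Mb on chromosome 4 and 13.5 kb per Mb on chromosome 19. The intervals treat peaks as independent and cover counting error only.

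**Figure D1:**
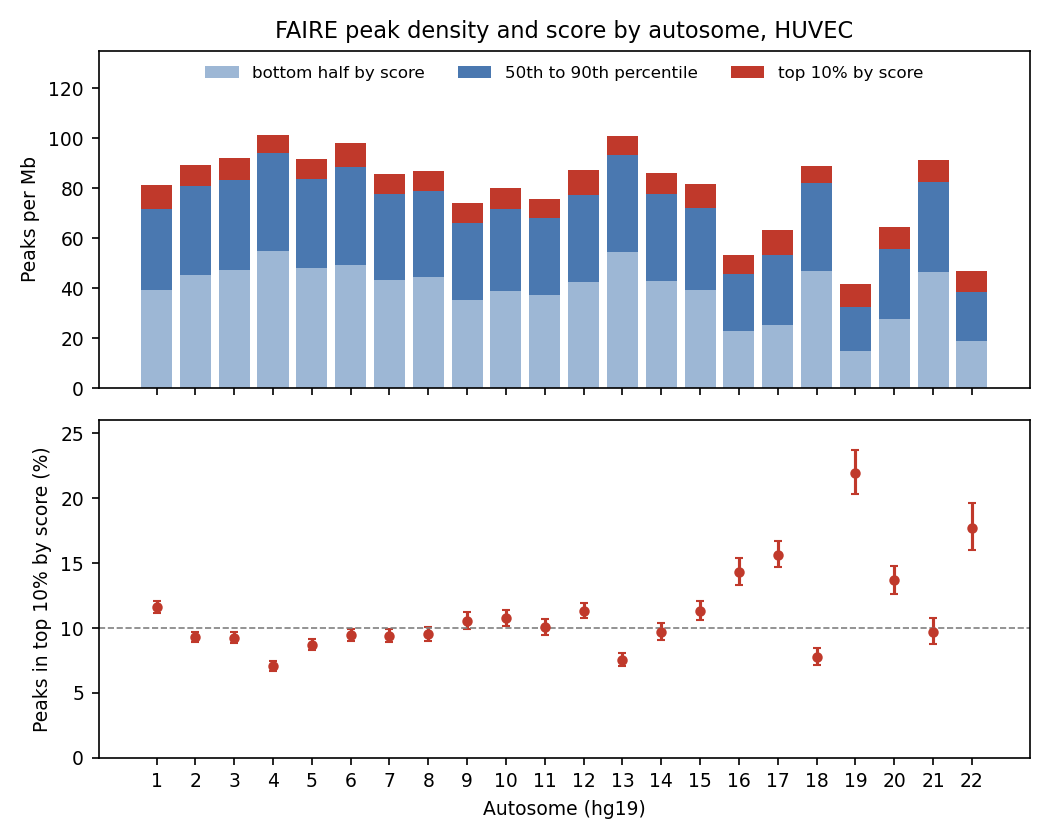
Upper panel, stacked bars of peaks per Mb (vertical axis) on each autosome (horizontal axis), divided by score into the lower 50%, the 50th to 90th percentile and the top 10%. Lower panel, percent of each autosome's peaks in the top 10%, with 95% Wilson intervals as error bars and a dashed line at 10%: chromosome 19 is sparse in peaks, and 21.96% of them are in the top 10%.

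Peaks clustered along the chromosomes. Of neighbouring peaks, 18.8% had midpoints within 2 kb of each other, against 13.95% on average in 100 uniform placements of the same peaks (range 13.8 to 14.1%), a fold of 1.35. The fold was 3.53 among the peaks of the top 10% alone, and differences in density between regions were not taken out of it. Within 1 kb the share was 9.92% against 5.92%. Long empty intervals were also more frequent than in the placements, with 1561 neighbouring pairs over 100 kb apart and at most 184 in any placement. Assembly gaps and poorly aligned sequence shorter than 1 Mb were not left out of the placements, and may account for part of this. The median distance between neighbours was 7203.5 bp, and 8134 bp in the placements.

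The density of pairs of peaks stepped up at a separation of about 5 kb. Relative to a uniform density of 1, it was 0.835 at 2.5 to 4.5 kb and 1.29 at 5.5 to 7.5 kb. The ratio was 0.645 (jackknife SE over 22 autosomes 0.0078), and it was below 1 on 22 of 22 autosomes. The ratio lay between 0.984 and 1.01 in the placements. The step was largest for low-scoring peaks around high-scoring ones. For the lower 50% of peaks the ratio was 0.685 (SE 0.011) around other peaks of the lower 50%, 0.524 (SE 0.014) around peaks from the 90th to the 99th percentile and 0.237 (SE 0.029) around the top 1%, where 88 pairs were counted below the step and 372 above it, densities of 0.230 and 0.972. Around the top 1%, the ratio was below 1 on 20 of 22 autosomes and ranged from 0 to 2. Among peaks of the top 10%, the ratio was 0.769 (SE 0.026), and it was below 1 on 18 autosomes. Pairs of these peaks exceeded the uniform density on both sides of the step, at 2.08 and 2.70.

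**Figure D2:**
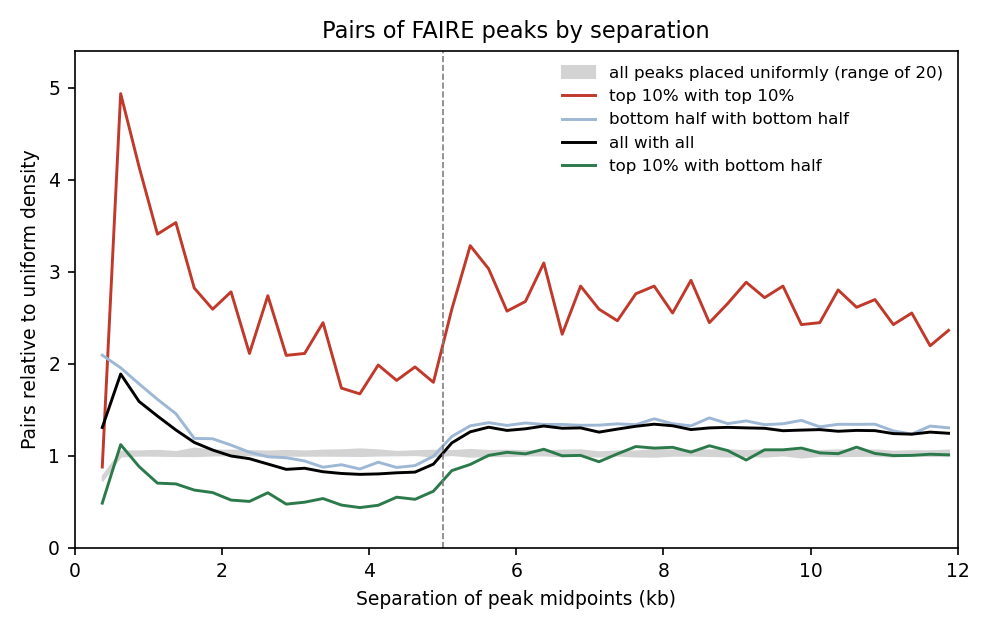
Density of pairs of peaks relative to a uniform density of 1 (vertical axis) against the separation of their midpoints in kb (horizontal axis), for pairs within and between score classes, with a dashed line at 5 kb. The grey band is the range of 20 uniform placements of all peaks; between 5.5 and 7.5 kb the density was 2.70 for pairs within the top 10% and 1.01 for pairs of a top 10% peak with a peak of the lower 50%.

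High-scoring peaks lay beside each other. Of the top 10%, 33.9% had another top 10% peak within 10 kb, against 17.9% on average when scores were exchanged at random among the peaks of each chromosome (range of 100 relabellings 17.2 to 18.7%), a fold of 1.89. Scores were exchanged over whole chromosomes, so the fold and the runs below also take in wider regions rich in high-scoring peaks. Pairs of top 10% peaks had a density of 1.75, relative to uniform, even at 50 to 100 kb. Runs of 5 or more such peaks, each midpoint at most 10 kb from the next, numbered 43, against a mean of 2.37 and a maximum of 7 in the relabellings. These runs held 230 peaks, or 1.01% of the top 10%, so most high-scoring peaks lay outside them. Pairs of a top 10% peak with a peak of the lower 50% had a density of 0.502 at 2.5 to 4.5 kb. At 5.5 to 7.5 kb it was 1.01. The relabelling kept the listed positions and did not take out this shortage, which may affect the fold and the number of runs.

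The largest runs had 8 top 10% peaks each. The run at chromosome 1, 85779518 to 85810063, was 30.5 kb long with a median score of 35.5 and a highest score of 75.6. That at chromosome 15, 60662527 to 60701015, was 38.5 kb long with a median score of 28.1. In both, 8 of the 9 listed peaks were in the top 10%. Intervals within 500 bp were not merged for the runs or the relabelling fold, so split intervals may raise both. The chromosome 1 run, for example, counts 85785493 to 85786333 and 85786616 to 85786868 as separate peaks. Weak peaks near strong ones may be under-listed, so the share of high-scoring peaks in these and the other runs may be overstated. A run of 7 lay at chromosome 9, 68408224 to 68439995, beyond a peak-free stretch that ended at position 65594704. Runs of 6 included chromosome 19, 45091067 to 45112067, where all 6 listed peaks were in the top 10%, and chromosome 1, 150577166 to 150602383, with a highest score of 92.2. Runs of 6 also lay close before peak-free stretches, at chromosome 21, 11065523 to 11094514 (stretch from 11187933), and chromosome 2, 89867283 to 89879332 (stretch from 90516142). The fourth highest peak of the list, on chromosome 10, belonged to a run of 5 at 65451998 to 65480067.

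**Figure D3:**
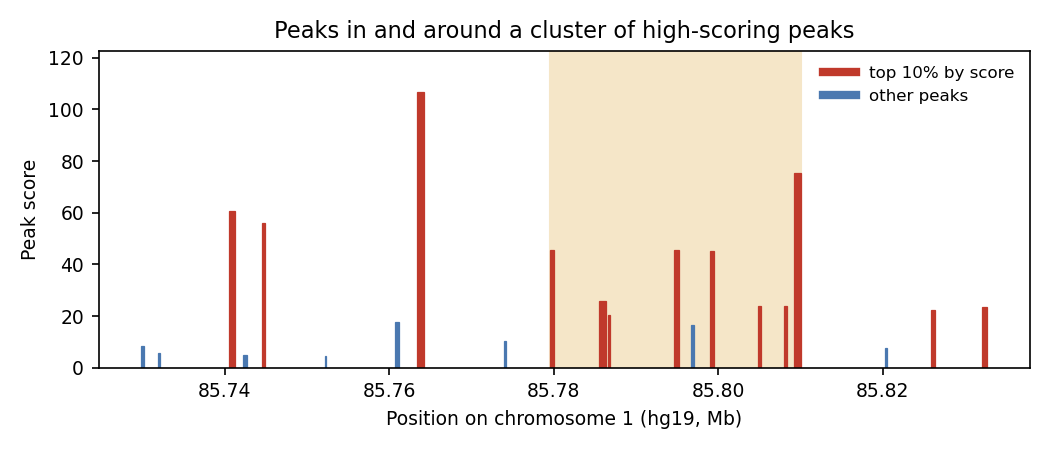
Peaks along chromosome 1 in hg19 coordinates (horizontal axis, Mb), each drawn as a bar over its interval with the authors' score as its height (vertical axis), red for the top 10% by score and blue for other peaks. The shaded run from 85779518 to 85810063 holds 8 red peaks and 1 blue one, and a red peak scoring 106.69 stands outside it at 85763405 to 85764211.

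Across 2644 windows of 1 Mb, the number of peaks ranged from 4 to 168 with a mean of 84.6 and an SD of 31.1. The SD was at most 17.3 in the placements. The windows richest in peaks were chromosome 10, 4 to 5 Mb, with 168 peaks (95% exact Poisson interval 144 to 195), chromosome 6, 75 to 76 Mb, with 167, and chromosome 4, 162 to 163 Mb, with 160. The richest in high-scoring peaks was chromosome 12, 96 to 97 Mb, with 39 of the top 10% (27.7 to 53.3) among 140 peaks, followed by windows on chromosomes 1 (68 to 69 Mb), 3 (194 to 195 Mb) and 11 (86 to 87 Mb) with 35 each. Both intervals treat peaks as independent and cover counting error only. They take no account of the choice of these windows as the highest. Of the windows richest in peaks, that on chromosome 10 held 31 of the top 10%, that on chromosome 6 held 16 and that on chromosome 4 held 6. Only 4 peaks were listed at chromosome 1, 18 to 19 Mb, and at chromosome 17, 72 to 73 Mb. In total, 61 windows held fewer peaks than the emptiest window of any placement, which had 21. Assembly gaps shorter than 1 Mb were not left out and may lie in such windows. At the other end, the fullest placed window had 147 peaks on average and 168 at most, and 99 of 100 placements stayed below 168. In 90 of 100 placements that window lay on chromosome 21. The placed maximum therefore says little about how full a window on chromosomes 10, 6 or 4 would be under uniform placement. The outcome changed with the start of the windows. When they were shifted by 500 kb, chromosome 14, 19.5 to 20.5 Mb, held 214 peaks and chromosome 6, 56.5 to 57.5 Mb, held 170, both above the fullest window of placements counted in the same way (163).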

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

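The alternatives with the lower 50% of peaks, 250 kb stretches, other relabelling distances and shifted windows, and all those of the pair density ratio, were chosen after seeing the data. Among the top 10% by score, the density ratio of chromosome 4 to chromosome 19 turned round, from 2.42 to 0.780. It was 1.72 in the top 50% and 3.68 in the lower 50%. A stricter score limit by construction lowered the number of peaks to 113479 (top 50%) and 22688 (top 10%) and raised the median score to 10.42 and 33.61. Median width rose to 318 and 418 bp, and rho of width with score was 0.436 and 0.383. The other 13 alternatives kept the direction. For the shifted windows, counted among them, this means only that the highest count did not fall, since its place changed. The spacing and relabelling alternatives stayed beyond their placements or relabellings. The excess of neighbours within 2 kb was 1.54-fold in the top 50%, 3.53-fold in the top 10%, 1.27-fold after merging and 1.31-fold without stretches of 250 kb. The pair density ratio stayed below 1, at 0.662 to 0.769, and the fold of top 10% peaks beside each other at 1.22 (50 kb) to 2.18 (2 kb). Shifting windows by 500 kb moved the highest count from chromosome 10 (168, equal to the placed maximum) to chromosome 14, 19.5 to 20.5 Mb (214, above a placed maximum of 163). Leaving out a replicate was not run because the list marks none. No paired analysis was possible because there is 1 group and 1 list. The alternatives set beforehand for promoters, gene lists, CpG content, motifs and GGAA repeats were not run. Unknown depth limits any statement on which weak peaks a deeper library would list.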

Other observations

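The tests of explanations below for the autosomes, and those of merging and local background for the spacing, were chosen only after the result was seen. The test of megabase density and both tests on chromosome 21 were set before it. The design has 1 group, so no biological explanation was tested.

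Windows rich in high-scoring peaks were not in excess among those rich in other peaks. Of 2644 windows of 1 Mb, 306 were in the upper 10% by number of top 10% peaks and 273 by number of other peaks. Both applied to 29 windows, against 31.6 for independent lists, and Spearman's rho of the counts was 0.130 across windows, which are not independent replicates. Another 151 windows held no top 10% peak although their median number of peaks was 78. The widest peak of the list, 2267 bp, lay at chromosome 21, 11141241 to 11143507, with a score of 61.2. The longest peak-free stretches were 21.2 Mb on chromosome 1, 18.3 Mb on chromosome 9 and 11.3 Mb on chromosome 16.

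Autosomes sparse in peaks had larger shares of high-scoring peaks, with chromosomes 4 and 19 at the ends, which largely restates the difference in peak density. Low-scoring peaks scattered uniformly would vary between megabases as placed peaks do, but over 1565 windows with an upper 50% peak in every 100 kb the variance over mean of lower 50% peaks, around each autosome's own mean, was 4.34, against at most 1.43 in 100 placements (an earlier test, the share of lower 50% peaks within 2 kb of a top 10% peak, was 0.810 times the placements and is affected by the step in pair density near 5 kb). This variance leaves out differences between autosomes, so it bears only on scatter within each autosome. Scatter uniform over all autosomes would give equal densities of lower 50% peaks. These were 55.0 per Mb on chromosome 4 and 14.9 on chromosome 19, so the lower 50% was not spread evenly over these autosomes. Both densities are part of the pattern to be explained and are no separate test. Stretches without callable sequence would leave occupied 100 kb windows alike, but the ratio of chromosome 4 to 19 in them was 2.275. Peak-free stretches of 1 Mb or more had already been left out, so this ratio bears only on empty windows of 100 kb. It lay near that of peaks per Mb, so such windows account for little of the difference. Uncallable sequence inside occupied windows was not tested. Merging of neighbouring sites would leave covered sequence alike, but the ratio of chromosome 4 to 19 was 2.357. With median widths of 276 and 280 bp on these chromosomes, the ratio of covered sequence mostly repeats that of peaks per Mb (2.42). A background raised within 5 kb of high-scoring peaks would spare sequence farther away, where the ratio was 3.689. That sequence was 175.7 of 188.0 Mb on chromosome 4 and 50.4 of 55.1 Mb on chromosome 19. The ratio therefore had to lie near that of all lower 50% peaks (3.68) and is no separate test. It shows only how small a part of the sequence lay within 5 kb of such peaks. Base composition, mappability and copy number were not tested and stay open, so the pattern may still be technical.

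The highest-scoring peak stood before the longest peak-free stretch of chromosome 21. If scores were raised throughout that part, a candidate explanation, the share of top 10% peaks there would be at least 2 times that after the stretch, and it was 1.98 times (95% interval 1.49 to 2.64), which leaves the question open. The interval treats peaks as independent, although top 10% peaks lay beside each other. If scores were raised beside every stretch of 1 Mb or more, the top 0.1% of peaks would be found within 1 Mb of one at least 2 times as often as all peaks. The ratio was 1.064 (95% interval 0.363 to 3.07), from 3 of 227 peaks, too few to decide. The highest-scoring peak itself ended at 9825733, over 1 Mb before the stretch from 11187933, so this test could not bear on it. Reads shared with repeated sequence were not tested.

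Peaks had an excess of neighbours under 2 kb and a step in pair density near 5 kb. Differences in density between megabases do not account for the whole excess, since the fold over placement within 1 Mb windows was 1.243, nor do open regions split into intervals within 500 bp of each other, since the fold was 1.266 after merging (an earlier form of this test, in which placements could lie closer than the merging allowed, was void). Each of these explanations was taken out alone, and what both together leave of the excess was not tested. Differences in density within a megabase were not taken out. The step also stayed after merging, with a ratio of 0.6796 against 0.982 to 1.02 in placements. A candidate explanation is a peak caller's local background, estimated in a window of 5 kb to either side, which a strong neighbour raises: the ratio for lower 50% peaks differed by -0.448 (SE 0.031) between surroundings of the top 1% and of the lower 50%. The SE treats the 2 ratios as independent, although they share the lower 50% peaks and the autosomes. The ratio around the lower 50% was itself 0.685, so the step was not limited to surroundings of high-scoring peaks. Pairs of a top 10% peak with a lower 50% peak had a density of 0.502 just below the step. Closer in, it was 1.12 at 500 to 750 bp and 0.883 at 750 to 1000 bp. At 250 to 500 bp it was 0.485, where placements of all peaks also fell, to 0.760. A raised background alone leaves the rise at 500 to 1000 bp unexplained. The explanation is a hypothesis from the same data, since the settings of the peak caller and its use of a control are not given in the sources used here, and weak peaks near strong ones may be under-listed.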
